A study of Mus musculus with 6 samples.

How the data were processed

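RNA from 6 sorted erythroblast samples of day 10.5 mouse embryos was measured by polyadenylated RNA sequencing, 3 Setd8 null and 3 control. The values used are gene counts that the authors deposited as 1 table per library, whole numbers per gene symbol with no normalization. Per the submitters' processing notes, the tools named for the series were FastQC, Trimmomatic (version 0.32), TopHat2 (version 2.1.0), HTSeq (version 0.6.1) and edgeR, with genome build mm9; their order, options and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads from genes that overlap on opposite strands cannot be told apart. Extraction used a small-input RNA kit, per the labels' protocols.

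The tables came in 2 forms, which coincided with the presence of a trailing letter in the sample titles. The 3 deposited tables of the unlettered set had a header line, the counter's summary lines and 25 symbols turned into dates, which were mapped one to one to the March and Septin gene families; the 3 tables of the lettered set had none of these. Summary lines that name no gene were kept out of library sizes and tests. In the unlettered set, reads assigned to no feature made up 42.9%, 7.72% and 6.07% of the table totals in control replicates 1 and 2 and null replicate 1, and reads without a unique alignment 24.1%, 22.5% and 32.4%. Ambiguous reads made up 0.657%, 2.17% and 2.35% in the same order. The assigned counts ranged from 7756940 to 21434719 per library, so that 3 counts correspond to 0.387 CPM in the shallowest and 0.140 CPM in the deepest. All sample columns were used. The transcripts of the mitochondrial genome, a fixed list, had no symbol among those used here and were not analysed. No pair of libraries of a group was a duplicate, since counts of same-group pairs differed by a chi-square of 21.9 to 369.1 per degree of freedom.

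Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group factor (10512 genes), libraries were scaled by TMM factors, dispersions were estimated with estimateDisp, and the groups were compared by glmQLFit with robust=TRUE and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment at 0.05. The test with group as the only term, the lists, the rule for named genes and the same test with the title set as a further term were all fixed before the data were examined. The fit with group alone had 4 residual degrees of freedom and a common coefficient of variation of 0.613, and the set-adjusted fit 3 and 0.399. CPM values are TMM-scaled and given as mean ± SD of 3 libraries. Ratios within a title set are differences of mean log2 CPM with a prior count of 2. Nothing in the labels says that replicates came from separate embryos, so the p-values measure the spread between these samples, which may be technical in part. Lower bounds of folds rest on 3 counts over the control group, and ratios against 1 to 3 control counts carry an exact 95% binomial interval; both cover counting error only. Leaving out a library of the set-adjusted fit leaves 2 residual degrees of freedom, and the spread is then pooled over the remaining libraries. Without null replicate 1 the unlettered set has no null library, and without control replicate 3 the lettered set has no control. That set then no longer compares the groups, so fewer calls in these fits may reflect the lost comparison and not an influential library.

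Of the 32 lists fixed in advance, 28 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 28 lists; camera with an estimated correlation and fry were run beside it. Camera sets the members of a list against all other tested genes, so its higher and lower are relative to those. The median log2 ratio of all tested genes was 0.13 with group alone and 0.044 set-adjusted. With group alone, camera called 13 lists higher and 6 lower, set-adjusted 13 and 5. With an estimated correlation 0 lists passed in either fit (12 with group alone and 6 set-adjusted at unadjusted p under 0.05). Fry gave 13 and 6 in both. With group alone the estimate lay below the preset 0.01 for the condensin and cohesin (0.00083), NRF2 (-0.0036) and inflammatory (-0.058) lists. These lists lost their call as well, so the loss does not measure correlation between genes alone. The filter kept genes with enough reads in a single group, so genes near 0 in controls were tested only where null libraries had reads. This favours higher values in lists that controls hardly expressed. Tested were 6 of 17 endothelial, 11 of 22 macrophage, 11 of 25 inflammatory, 15 of 35 interferon and 16 of 30 progenitor genes. Of the other markers, 6 of 15 megakaryocyte, 4 of 14 mesenchymal, 3 of 12 neural or epithelial and 2 of 15 granulocyte and mast cell genes were tested. Tested as well were 1 of 20 hepatic genes and 2 of 6 genes of definitive red cells. The p53 list had 45 of 51 tested. The lists cover globins, heme and iron genes, red cell membrane genes, erythroid factors, progenitor genes, late maturation, lysine 20 methylation of histone H4, condensin and cohesin, p53 targets, DNA damage, the G1/S and G2/M transitions, kinase inhibitors, apoptosis, interferon, inflammation, stress, NRF2, ribosomal proteins, glycolysis, oxidative phosphorylation, replication histones, the mitochondrial genome, sex-linked genes, and markers of definitive red cells, macrophages, granulocytes and mast cells, megakaryocytes, endothelium, hepatic endoderm, mesenchyme, and neural and epithelial cells.

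The text names Setd8, Gata2, Cdkn1a, Mdm2, Gata1 and Klf1 whatever their values; the 8 genes with the largest log2 ratios in each direction among called genes whose groups did not overlap and whose mean was at least 5 CPM; up to 4 called members per list by smallest adjusted p; and the 2 members with the highest mean CPM in a list without a call, except lists of other cell types. For the set-adjusted fit, the rule for the largest ratios and up to 2 further called members per list were added after the data were examined. One gene that the rule selects is not reported here. The adult alpha globin copies Hba-a1 and Hba-a2 are near-identical in sequence and were not among the tested genes.

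The procedure was tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed by known folds. The differences between title sets and the trended dispersions of the set-adjusted fit were built in. The simulated counts thus followed the set-adjusted model, so a lower recovery with group alone was in part fixed in advance and does not rank the tests. Of 9586 simulated genes that passed the filter, the test with group alone recovered 0% of genes changed 2-fold or 4-fold, and 18.2% of those raised and 9.09% of those lowered 8-fold. The set-adjusted test recovered 35.3% and 18.2% at 2-fold, 64.7% and 42.4% at 4-fold and 93.9% and 69.7% at 8-fold, for raised and lowered genes, with 4 unchanged genes among its calls.

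The alternatives were RLE, upper-quartile and unscaled library totals, removal of globin genes, DESeq2 1.42.0, edgeR's exact test, limma-voom with quality weights, a non-robust fit, no low-count filter, a filter of 10 counts in every library, the title set as a term, and each library left out. Sex, read from the Y-linked genes, was added as a term after the data were examined, as were the alternatives of the set-adjusted fit other than its list tests. GC content, length and opposite-strand overlap came from the GENCODE M21 annotation, in which 22797 of 23284 symbols had a match; since its build differs from that of the counts, it gave no coordinates.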

Results

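Polyadenylated RNA was sequenced from mouse erythroblasts, the nucleated precursors of red cells, at embryonic day E10.5. Cells were sorted as positive for Ter119, a surface antigen of the red cell lineage, and for CD71, the transferrin receptor. The design text of the series names fetal blood as the source, and the sample labels name fetal liver. The Setd8 null group held 3 libraries from embryos with floxed Setd8 alleles and Cre recombinase expressed from the Epor locus, which is active in erythroid cells. The control group held 3 libraries, 2 with Cre and wild-type Setd8 (control replicates 1 and 3) and 1 with floxed alleles and no Cre (control replicate 2). Setd8, now also named Kmt5a, encodes the enzyme that places a single methyl group on lysine 20 of histone H4. The comparison asked how the transcriptome of these erythroblasts differed without Setd8, and the title of the series names the cell cycle and chromatin condensation during maturation as the subject.

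Gene counts summed to 7756940, 21434719 and 19806956 reads in control replicates 1, 2 and 3, and to 21381086, 16547029 and 15203019 in null replicates 1, 2 and 3. Globin genes took 45.2%, 44.4% and 37.1% of the control counts and 39.9%, 28.3% and 26.5% of the null counts. The libraries fell into 2 sets by their titles, which carried no trailing letter for control replicates 1 and 2 and null replicate 1 (the unlettered set) and a letter for control replicate 3 and null replicates 2 and 3 (the lettered set). Between the sets, 3001 of 10512 tested genes differed by edgeR's quasi-likelihood test with group in the model, 1142 of them higher and 1859 lower in the unlettered set. The erythroid factor Klf1 followed this split, at 87.6 and 66.9 CPM (counts scaled to 1000000 per library) in control replicates 1 and 2 and 75.2 in null replicate 1, against 715 in control replicate 3 and 543 and 604 in null replicates 2 and 3. Each comparison was made with group alone, and again with the title set as a term, called set-adjusted here. Y-linked transcripts were present in all 3 null libraries and in control replicate 1, and near 0 in control replicates 2 and 3, where Xist, the X inactivation transcript, stood at 208 and 104 CPM, so that 2 of 3 controls lacked Y-linked transcripts and no null library did. Null replicate 2 had Xist at 9.70 CPM beside its Y-linked transcripts (1.64 and 0.155 in null replicates 1 and 3), and whether a library pools several embryos is not given in the sources used here.

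Setd8 itself was counted in every library, with 499, 1405 and 4375 reads in control replicates 1, 2 and 3 and 837, 1953 and 1864 in the null replicates. In the unlettered set it stood at 73.9 and 74.8 CPM in the controls and 48.9 in the null library, and in the lettered set at 203.5 CPM in the control and 100.3 and 96.4 in the null libraries. With group alone the log2 ratio of null to control was -0.52 (SE 0.49, adjusted p = 0.702, edgeR quasi-likelihood with Benjamini-Hochberg), and Setd8 did not pass. Set-adjusted, it fell by 0.83 on the log2 scale (SE 0.17, adjusted p = 0.00911). Without control replicate 3 the group-alone log2 ratio was 0.066 and the set-adjusted one -0.62 (adjusted p = 0.134), and with title set and sex as terms it was -0.72 (adjusted p = 0.2345), so that Setd8 did not pass in these fits. Counts over the whole gene may include exons outside the floxed part, and reads were not counted per exon. The remaining reads therefore need not measure intact transcript.

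By camera, targets of p53, the transcription factor of the DNA damage response, had the smallest p of all lists in both fits, and most of them were higher in null cells; by fry with group alone it was the apoptosis list (adjusted p = 0.000657, against 0.00249 for the p53 targets). Cdkn1a, the cell cycle inhibitor p21, rose from 9.69 ± 3.79 CPM in controls to 735 ± 189 in null cells (SD, n = 3 each; log2 ratio 6.25, SE 0.48, adjusted p = 0.00667 by edgeR quasi-likelihood with Benjamini-Hochberg). Mdm2, the ubiquitin ligase that degrades p53, rose from 25.5 ± 12.8 to 284 ± 43.2 CPM (log2 ratio 3.48, SE 0.42, adjusted p = 0.0189). Ccng1 rose from 46.8 ± 20.2 to 647 ± 217 CPM, Trp53inp1 from 1.28 ± 1.0 to 110 ± 14.4, Eda2r from 0.230 ± 0.186 to 27.0 ± 6.55, and Dcxr from 5.07 ± 2.40 to 176 ± 52.2. Of 45 tested targets of p53, 13 rose and 0 fell with group alone (32 rose adjusted over the list alone), and 29 rose and 0 fell set-adjusted (34 rose and 1 fell adjusted over the list alone). The median log2 ratio of the list was 2.33 with group alone and 2.17 set-adjusted. Camera called the list higher (adjusted p = 1.52e-34 with group alone and 1.79e-46 set-adjusted), and the adjusted p was 0.0607 and 0.172 with an estimated correlation. In 32 of the 45 genes every null library lay above every control library. With 1 library left out, 1 to 18 members rose with group alone, lowest without null replicate 2, and 19 to 29 set-adjusted, lowest without null replicate 1.

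**Figure D1:**
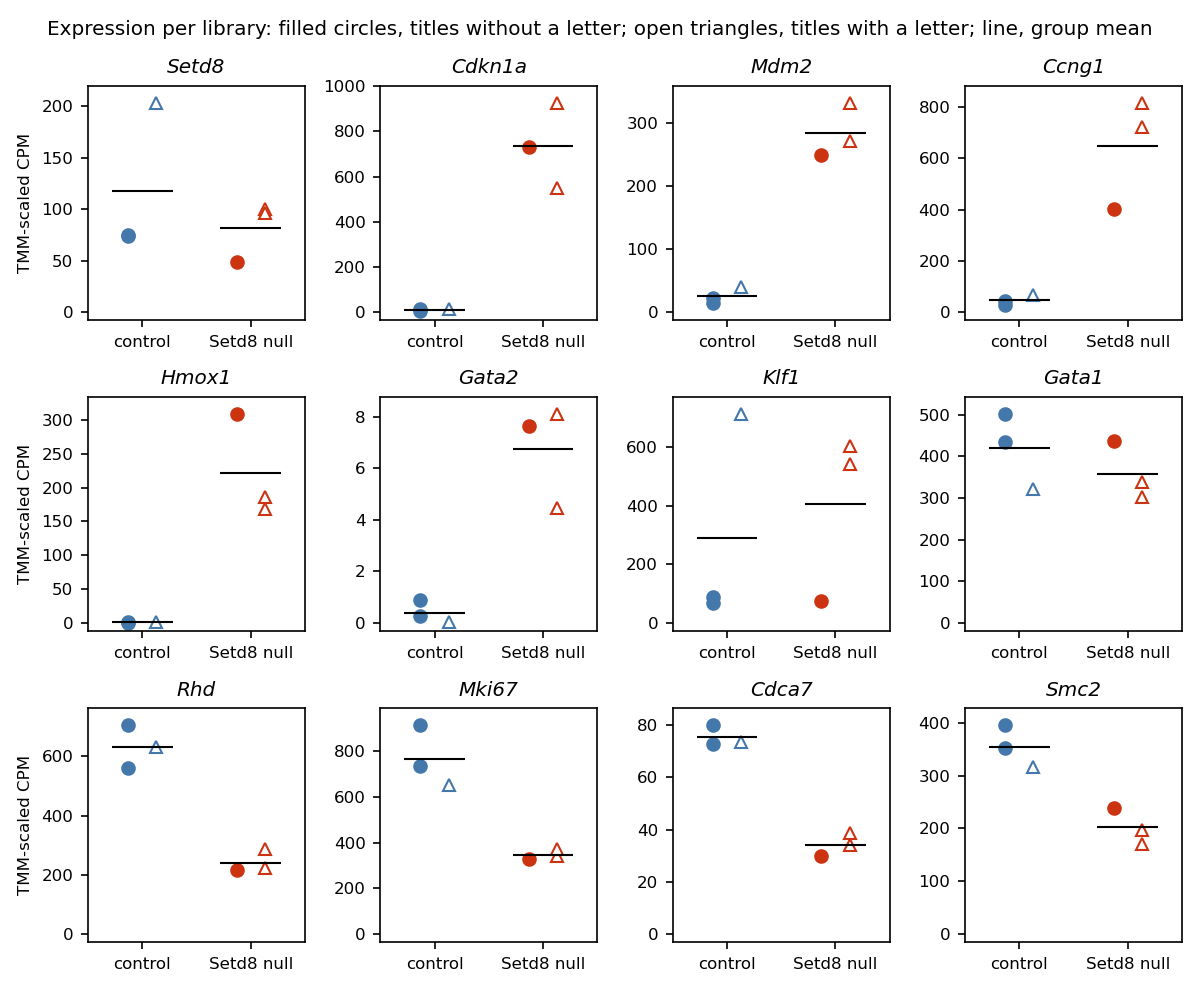
Expression of 12 genes in each library, in CPM scaled by TMM factors. Blue points are controls and red points Setd8 null libraries, filled circles the unlettered set, open triangles the lettered set, and each line a group mean of 3 libraries. Cdkn1a, Mdm2, Ccng1, Hmox1 and Gata2 lay higher and Rhd, Mki67, Cdca7 and Smc2 lower in every null library than in every control, while Klf1 separated the sets.

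Across all genes, 120 of 10512 were higher and 1 was lower in null cells with group alone, and all 121 changed more than 2-fold. Of the 8 genes with the largest ratios, 7 had no read in any control: Matn1, a cartilage matrix protein (at least 647-fold higher), Il1r2, a decoy receptor for interleukin 1 (263-fold), the mitochondrial creatine kinase Ckmt1 (198-fold), the neuronal calcium sensor Hpcal1 (197-fold), the death receptor Fas (189-fold), Clic6 (179-fold) and Creb3l1 (175-fold), each a lower bound against 3 counts over the control group. Ak1, an adenylate kinase, had 2 control reads and rose from 0.0333 ± 0.0290 to 84.9 ± 19.96 CPM, a ratio of 1981 with a 95% counting interval of 548 to 16360. The 1 gene that fell was D030028A08Rik, from 148 ± 16.5 to 36.9 ± 10.2 CPM (log2 ratio -2.00, SE 0.29, adjusted p = 0.0321 by edgeR quasi-likelihood with Benjamini-Hochberg). Set-adjusted, 909 genes were higher and 437 lower, 775 and 172 of them past 2-fold, and all 121 genes called with group alone were among them. The set-adjusted calls added Trpv2 (at least 213-fold) and added among the lower genes Plxnd1, a semaphorin receptor (9.96 ± 3.64 to 1.48 ± 0.838 CPM), the adenylate cyclase Adcy1 (11.1 ± 1.66 to 1.99 ± 0.805 CPM) and the urea transporter Slc14a1 (31.0 ± 12.2 to 6.39 ± 1.59 CPM). Ankrd27 fell by 1.82 on the log2 scale, Ppip5k2 by 1.94, Ccdc93 by 1.86 and Erlin2 by 1.85 in the same fit. Sdc4, a cell surface proteoglycan with no control read, was called in both fits and stood at least 168-fold higher.

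The title sets shared no library, and in each of them the null cells could be set against their own controls. Of all tested genes, 68.6% had the same direction in both sets, and the log2 ratios of the sets had a Pearson r of 0.633 across genes, which are not independent replicates. The 121 genes called with group alone and the 1346 called set-adjusted all did so, which a call over both sets favours by itself. For Cdkn1a the log2 ratio was 6.51 in the unlettered and 5.88 in the lettered set, for Mdm2 3.78 and 2.92, and for Setd8 -0.60 and -1.05. All null libraries lay above all controls for 14.9% of genes and below them for 9.16%, where chance gives 5% in each direction for exchangeable libraries, which these are not, given the title sets. With group alone the counts of higher genes were 23, 22 and 109 without control replicates 1, 2 and 3 and 41, 3 and 25 without null replicates 1, 2 and 3, and set-adjusted they were 622, 628, 625, 162, 523 and 869, with 223, 213, 180, 40, 235 and 734 lower. Outside the p53 targets, at most 3 members of any list rose with group alone in a fit without 1 library and 0 fell, with 0 mesenchymal markers higher in any of them. With sex as a term beside group 0 genes passed (edgeR quasi-likelihood, 915 at unadjusted p under 0.05), and with title set and sex together 161 were higher and 62 lower. Control replicate 1, the shallowest library, was the only control with Y-linked transcripts. With sex beside group, the null libraries were therefore set against that library alone, and the lost calls do not show that sex carries the changes. Cdkn1a stood at 11.7 CPM there, against 729, 927 and 550 in null replicates 1, 2 and 3.

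**Figure D2:**
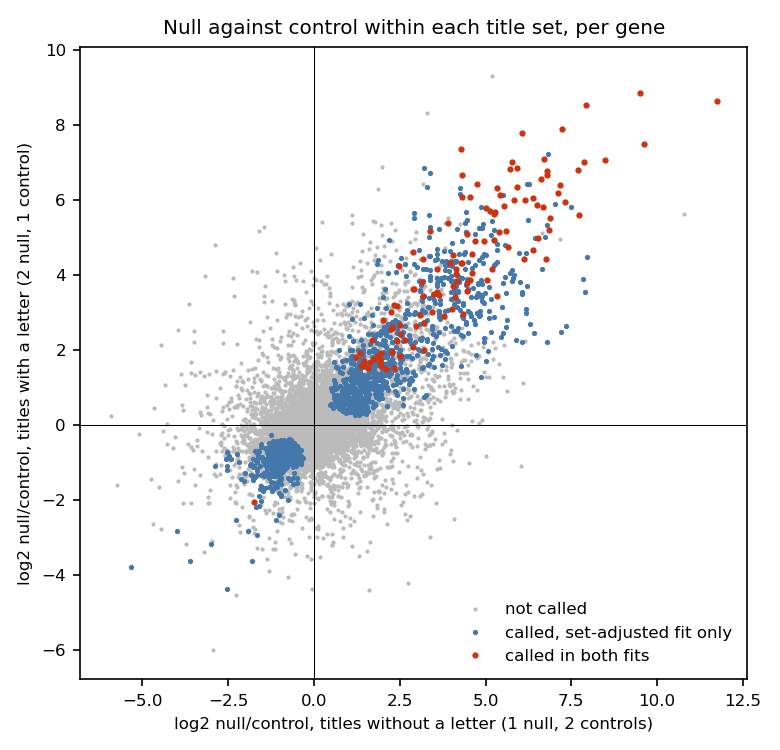
Log2 ratio of null to control for each of 10512 tested genes, in the unlettered set on the horizontal axis (1 null and 2 control libraries) and in the lettered set on the vertical axis (2 null and 1 control libraries). Grey points were not called, blue points were called set-adjusted alone, and the 121 red points were called in both fits. All called genes lie in the upper right or lower left quadrant, which calls made over both sets favour.

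Camera placed genes of mitosis and of DNA replication lower in null cells at the preset correlation and called neither list with an estimated one, and most single genes did not pass in either fit. Mki67, the proliferation antigen Ki-67, stood at 767 ± 135 CPM in controls and 347 ± 21.4 in null cells, and fell by 1.10 on the log2 scale set-adjusted (SE 0.17, adjusted p = 0.00203, edgeR quasi-likelihood with Benjamini-Hochberg; adjusted p = 0.0995 with group alone). Of 60 genes of mitosis and the G2/M transition, 1 rose and 0 fell with group alone (3 rose and 8 fell adjusted over the list alone), and 3 rose and 21 fell set-adjusted (4 and 35 adjusted over the list alone). The genes that rose included Psrc1, a p53-inducible spindle protein (8.86 ± 3.0 to 99.1 ± 19.2 CPM, called in both fits), and the phosphatase Cdc25b (236 ± 17.7 to 498 ± 57.8 CPM, set-adjusted). Camera called this list lower (adjusted p = 7.82e-07 with group alone, 5.19e-09 set-adjusted), with adjusted p = 0.0607 and 0.182 with an estimated correlation. Of 59 genes of DNA replication and the G1/S transition, 1 rose and 0 fell with group alone, also adjusted over the list alone, and 1 rose and 14 fell set-adjusted (1 and 25 adjusted over the list alone). Cyclin D2, Ccnd2, was the gene that rose, from 89.8 ± 5.21 to 261 ± 39.6 CPM, and Cdca7 (log2 ratio -1.18, SE 0.20, 75.5 ± 4.04 to 34.3 ± 4.40 CPM) and the deubiquitinase Usp1 (log2 ratio -1.20, SE 0.18) fell set-adjusted. Camera called this list lower as well (adjusted p = 7.82e-07 and 2.61e-09), with adjusted p = 0.0958 and 0.242 with an estimated correlation. With 1 library left out, 5 to 29 mitosis genes fell set-adjusted, lowest without control replicate 3, and 3 to 25 replication genes, lowest without null replicate 1.

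Of 20 condensin and cohesin genes, whose products compact and hold together chromosomes, none passed with group alone (0 higher and 3 lower adjusted over the list alone), and 9 fell and 0 rose set-adjusted (0 and 13 adjusted over the list alone). The condensin subunit Smc2 stood at 355 ± 40.1 CPM in controls and 202 ± 33.5 in null cells and fell by 0.71 on the log2 scale (SE 0.15), and the cohesin subunits Stag2 and Stag1 fell by 1.21 (SE 0.23) and 1.32 (SE 0.28). Smc4 had a log2 ratio of -0.51 (SE 0.17) and did not pass. Camera called the list lower (adjusted p = 1.47e-05 with group alone and 1.49e-06 set-adjusted), with adjusted p = 0.0607 and 0.172 with an estimated correlation. Among 20 enzymes, readers and degradation factors of histone H4 lysine 20 methylation, 0 passed with group alone, also adjusted over the list alone, and set-adjusted 1 rose and 2 fell (1 and 5 adjusted over the list alone). The methyltransferase Suv420h2, which adds further methyl groups to this residue, rose from 34.0 ± 13.7 to 80.1 ± 26.4 CPM (log2 ratio 0.97, SE 0.22), and Skp2, a subunit of a ubiquitin ligase, fell from 16.7 ± 5.25 to 6.82 ± 1.35 CPM. Pcna stood at 402 ± 25.1 and 357 ± 66.3 CPM and Skp1a at 301 ± 36.3 and 348 ± 8.54, neither of which passed. Camera gave this list an adjusted p of 0.390 and 0.144. With group alone its median log2 ratio was 0.12, against 0.13 over all tested genes, while camera, which compares with the other genes, pointed lower. The median of this list ran from -0.099 to 0.18 with 1 library left out. Without null replicate 3, 1 of these genes rose and 5 fell set-adjusted, and at most 1 passed without any other library. Of 45 genes that sense and repair DNA damage, 0 passed with group alone, also adjusted over the list alone, and 4 fell set-adjusted (1 adjusted over the list alone). They included H2afx, the histone variant phosphorylated at DNA breaks (log2 ratio -1.67, SE 0.21), whose counts also differed between the sets (7.71 and 6.02 against 224 CPM in the controls), and the checkpoint kinase Chek1 (log2 ratio -1.17, SE 0.31). Tipin stood at 231 ± 26.4 and 181 ± 44.2 CPM and Rpa1 at 168 ± 48.0 and 138 ± 32.4, and neither passed. Camera called this list lower (adjusted p = 0.000415 and 6.09e-05), with adjusted p = 0.0607 and 0.172 with an estimated correlation. Over the fits without 1 library, 0 to 12 condensin and cohesin genes fell set-adjusted, lowest without null replicate 1, and of the DNA damage genes 1 fell without control replicate 1, control replicate 2, null replicate 1 or null replicate 2, 2 without control replicate 3 and 6 without null replicate 3.

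Some genes of cell death and stress rose, in part the p53 targets counted above, and most did not pass. Of 35 apoptosis genes, 2 rose with group alone (6 adjusted over the list alone), and 7 rose and 1 fell set-adjusted (9 and 2 adjusted over the list alone). Beside Fas, the gene for Noxa, Pmaip1, rose from 1.34 ± 0.502 to 35.0 ± 14.8 CPM in both fits. Bax, which permeabilises mitochondria, rose from 80.1 ± 32.7 to 261 ± 37.8 CPM, and the death receptor Tnfrsf10b from 3.15 ± 1.99 to 17.0 ± 14.5, both set-adjusted. Fas, Pmaip1, Bax and Tnfrsf10b are all on the list of p53 targets as well, as are Cdkn1a and Sesn2, given below. Their calls repeat the p53 result and are not separate from it. By camera the adjusted p was 0.0162 and 0.0107, and 0.0958 and 0.182 with an estimated correlation. Of 5 cyclin-dependent kinase inhibitors, 1 rose, Cdkn1a, in both fits and adjusted over the list alone (camera adjusted p = 0.00717 and 0.000741; 0.0958 and 0.184 with an estimated correlation). Of 22 genes of the unfolded protein and integrated stress responses, 1 rose with group alone (4 adjusted over the list alone), and 6 rose and 2 fell set-adjusted (7 and 2 adjusted over the list alone). The transcription factor Atf3 had 1 control read and stood at 5.76 ± 1.5 CPM in null cells, a ratio of 273 with a 95% counting interval of 48.7 to 10830, and Sesn2 rose from 3.06 ± 3.93 to 47.2 ± 25.1 CPM and Ddit4 from 0.225 ± 0.149 to 8.63 ± 7.03, set-adjusted. By camera this list had adjusted p = 0.0114 and 0.0231, and 0.224 and 0.184 with an estimated correlation. When 1 library was left out, 3 to 6 apoptosis genes and 1 to 5 stress genes rose set-adjusted, both lowest without null replicate 1.

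Among antioxidant genes Hmox1, the heme oxygenase, rose from 0.912 ± 0.286 CPM in controls to 222 ± 76.4 in null cells (log2 ratio 7.90, SE 0.46, adjusted p = 0.00145 by edgeR quasi-likelihood with Benjamini-Hochberg). Nqo1, a quinone reductase, rose from 14.8 ± 4.71 to 57.6 ± 3.61 CPM. Set-adjusted, the ferritin light chain Ftl1 rose from 7474 ± 965 to 25440 ± 5266 CPM (log2 ratio 1.78, SE 0.19) and the peroxiredoxin Prdx1 from 914 ± 68.0 to 2771 ± 814 (log2 ratio 1.71, SE 0.16). Ftl1 has near-identical processed copies in the genome, and its counts are uncertain to the extent that reads were shared with them. Of 22 oxidative stress and NRF2 target genes, 2 rose with group alone (7 adjusted over the list alone) and 10 set-adjusted (11 adjusted over the list alone), and 0 fell. Camera called the list higher (adjusted p = 6.39e-05 and 1.61e-09), with adjusted p = 0.0607 and 0.172 with an estimated correlation. Of 19 glycolytic enzymes, 1 rose with group alone (4 adjusted over the list alone), and 8 rose and 1 fell set-adjusted (11 and 2 adjusted over the list alone). The lactate dehydrogenase subunit Ldhb had 1 control read and stood at 10.04 ± 2.27 CPM in null cells, a ratio of 469 with a 95% counting interval of 83.9 to 18560. Pyruvate kinase, Pkm2, rose from 205 ± 36.6 to 608 ± 148 CPM and Gpi1 from 103 ± 11.7 to 240 ± 32.1, set-adjusted. This list had camera adjusted p = 0.0346 and 8.93e-05, and 0.283 and 0.182 with an estimated correlation. Across the leave-one-out fits, 5 to 10 antioxidant and 4 to 9 glycolytic genes rose set-adjusted, both lowest without null replicate 1. Macrophage markers rose in the same libraries (5 of 11 set-adjusted), and a part of macrophages in these increases was not tested.

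A minority of interferon-stimulated and inflammatory genes rose in null cells. Of 15 interferon genes, 3 rose with group alone (3 adjusted over the list alone) and 5 set-adjusted (5 adjusted over the list alone), and 0 fell. Isg15 rose from 0.976 ± 0.444 to 21.8 ± 14.1 CPM, Bst2 from 1.86 ± 0.495 to 17.4 ± 3.78, and the peptide transporter Tap1 from 1 control read to 7.41 ± 4.16 CPM, a ratio of 355 with a 95% counting interval of 63.3 to 14050. Set-adjusted, Irf9 rose from 7.98 ± 2.73 to 17.9 ± 4.61 CPM and Ifitm3 from 0.0775 ± 0.134 to 2.53 ± 1.97, and neither passed in any fit with 1 library left out. By camera the interferon list had adjusted p = 0.000415 and 0.000843, and 0.0607 and 0.172 with an estimated correlation. Of 11 inflammatory and NF-kB response genes, 1 rose with group alone (3 adjusted over the list alone) and 4 set-adjusted (4 adjusted over the list alone), and 0 fell. Il1b had no control read and stood at least 110.4-fold higher, and Zfp36 (5.68 ± 1.93 to 23.4 ± 7.63 CPM) and Junb (3.87 ± 6.39 to 29.6 ± 24.8 CPM) rose set-adjusted. Junb also followed the title sets, and its groups overlapped. It stood at 0.148, 0.213 and 11.3 CPM in control replicates 1, 2 and 3 and 1.52, 48.2 and 39.2 in null replicates 1, 2 and 3. This list had camera adjusted p = 0.000343 and 0.00181, and 0.0607 and 0.182 with an estimated correlation. Macrophage markers moved with these genes, with Cd68 at 1.31 ± 0.28 CPM in controls and 15.2 ± 5.53 in null cells. With group alone, 0 interferon genes passed when any 1 library was left out. With null replicate 1 left out, 0 genes of either list passed set-adjusted, and at most 4 of each passed without any other library.

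Gata2, the factor of blood progenitors that is replaced by Gata1 during erythroid maturation, stood at 0.401 ± 0.437 CPM in controls and 6.75 ± 1.99 in null cells. It did not pass with group alone (log2 ratio 4.24, SE 1.05, adjusted p = 0.113, edgeR quasi-likelihood with Benjamini-Hochberg) and rose set-adjusted (log2 ratio 4.98, SE 1.04, adjusted p = 0.0102), though not without null replicate 1 (log2 ratio 6.86) or control replicate 3 (log2 ratio 3.83). Gata1 stood at 420 ± 90.6 and 359 ± 69.0 CPM and Klf1 had a set-adjusted log2 ratio of -0.18 (SE 0.16), and neither passed in either fit. Of 16 progenitor genes, 1 rose with group alone (5 rose and 1 fell adjusted over the list alone), and 5 rose and 1 fell set-adjusted (6 and 1 adjusted over the list alone). The adhesion receptor Cd44 had 3 control reads and stood at 5.59 ± 1.63 CPM in null cells, a ratio of 88.6 with a 95% counting interval of 30.03 to 432. Hhex rose from 0.473 ± 0.531 to 27.6 ± 17.9 CPM and Ikzf1, the factor Ikaros, fell from 117 ± 41.1 to 44.8 ± 19.5, set-adjusted. Camera gave the progenitor list adjusted p = 0.000641 and 0.00908, and 0.0958 and 0.242 with an estimated correlation. Of 24 erythroid transcription factors and cofactors, 0 passed with group alone, also adjusted over the list alone, and 2 rose and 2 fell set-adjusted (4 and 3 adjusted over the list alone). Nfe2 rose from 158 ± 26.9 to 258 ± 13.7 CPM, and Tcf3, which also followed the title sets, fell by 1.17 on the log2 scale (SE 0.31). Camera gave the factors adjusted p = 0.609 and 0.672, and its set-adjusted median (-0.088) and mean (0.086) log2 ratios differed in sign. With 1 library left out, 1 to 5 progenitor genes rose set-adjusted, lowest without null replicate 1, and 0 erythroid factors passed without null replicate 1 or null replicate 2. Macrophage, endothelial and megakaryocyte markers rose in the same libraries as the progenitor genes (5 of 11, 4 of 6 and 2 of 6 set-adjusted).

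Most genes of hemoglobin production did not pass. Of 4 tested globins, 0 passed with group alone, also adjusted over the list alone, and 1 fell set-adjusted, also adjusted over the list alone. That gene was the embryonic alpha-like globin Hba-x, at 117100 ± 26080 CPM in controls and 67150 ± 29120 in null cells (log2 ratio -0.60, SE 0.17, adjusted p = 0.0434 by edgeR quasi-likelihood with Benjamini-Hochberg), and it did not pass in any fit with 1 library left out. Hbb-y stood at 222800 ± 61470 and 162700 ± 92070 CPM and Hbb-bh1 at 115800 ± 14370 and 85860 ± 38140. The list had camera adjusted p = 0.05004 with group alone and 0.0850 set-adjusted. Of 22 genes of heme synthesis and iron uptake, 0 passed with group alone, also adjusted over the list alone, and 1 rose and 1 fell set-adjusted, also adjusted over the list alone. The transferrin receptor Tfrc, one of the sort markers, fell from 426 ± 24.0 to 244 ± 45.0 CPM (log2 ratio -0.92, SE 0.16), and the biliverdin reductase Blvrb rose by 0.64 on the log2 scale (SE 0.16). Alas2, the first enzyme of heme synthesis in red cells, stood at 2741 ± 395 and 2696 ± 315 CPM and did not pass. The list had camera adjusted p = 0.0959 and 0.102, while fry called it lower in both fits (adjusted p = 0.00325 and 0.0077). Of 23 red cell membrane and surface genes, 0 rose and 0 fell with group alone (0 and 2 adjusted over the list alone), and 1 rose and 4 fell set-adjusted (4 and 9 adjusted over the list alone). Rhd, a Rhesus antigen gene, fell from 633 ± 72.3 to 241 ± 38.5 CPM (log2 ratio -1.43, SE 0.17) and Epb4.9, which encodes dematin, from 118 ± 23.9 to 55.7 ± 4.08 (log2 ratio -0.97, SE 0.19). Car2 stood at 8020 ± 3652 and 8198 ± 4621 CPM and the band 3 gene Slc4a1 at 1862 ± 57.5 and 1402 ± 318, and neither passed. Camera called the list lower (adjusted p = 0.0263 and 0.0148), with adjusted p = 0.143 and 0.323 with an estimated correlation. With 1 library left out, 1 to 6 membrane genes fell set-adjusted, lowest without null replicate 1, where 0 heme and iron genes passed.

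Of 32 genes of nuclear condensation, enucleation and organelle clearance, 0 passed with group alone (3 rose and 1 fell adjusted over the list alone), and 8 rose and 2 fell set-adjusted (11 and 5 adjusted over the list alone). The small GTPase Rac2 rose from 10.3 ± 4.08 to 59.6 ± 20.2 CPM (log2 ratio 2.90, SE 0.25) and the autophagy gene Map1lc3b from 269 ± 97.3 to 501 ± 321 (log2 ratio 1.19, SE 0.18). The groups overlapped for Map1lc3b, at 360, 281 and 166 CPM in control replicates 1, 2 and 3 and 871, 345 and 287 in null replicates 1, 2 and 3. Its log2 ratio was 1.45 in the unlettered and 0.92 in the lettered set. Bpgm stood at 1021 ± 110 and 1440 ± 132 CPM and Ncoa4 at 780 ± 96.6 and 919 ± 267, and neither passed. The list had camera adjusted p = 0.0335 and 0.0368, and 0.412 and 0.394 with an estimated correlation. With 1 library left out, 1 to 8 members rose, lowest without null replicate 1. None of 76 ribosomal protein genes passed in either fit, also adjusted over the list alone, but 11 rose set-adjusted without control replicate 3 and 1 without null replicate 3. Rplp0 stood at 3347 ± 1325 and 3565 ± 2438 CPM and Rpl4 at 2700 ± 865 and 2466 ± 1182. Camera placed the ribosomal list lower than the other genes with group alone (adjusted p = 0.00422, and 0.734 with an estimated correlation) and in the opposite direction set-adjusted (adjusted p = 0.222). Its median log2 ratio with group alone was -0.12, and fry did not call it (adjusted p = 0.757). Of 64 nuclear genes of oxidative phosphorylation, 0 passed with group alone, and 2 rose set-adjusted, Cox4i1 (log2 ratio 0.70, SE 0.18) and Ndufb6 (log2 ratio 0.76, SE 0.19), with 0 adjusted over the list alone in either fit. Without control replicate 3, 15 of them rose set-adjusted, without null replicate 3, 5, and without any other library, 0. Atp5b (1087 ± 738 and 1356 ± 674 CPM) and Atp5a1 (841 ± 102 and 909 ± 119 CPM) did not pass, and the list had camera adjusted p = 0.910 with group alone and 0.0466 set-adjusted, the latter 0.750 with an estimated correlation. Of 26 replication-dependent histone genes, whose messages mostly lack a poly(A) tail and which share sequence with one another, 0 passed with group alone (1 rose adjusted over the list alone), and 3 rose and 1 fell set-adjusted, also adjusted over the list alone. Hist1h2bc rose from 6.29 ± 3.68 to 44.1 ± 14.8 CPM, Hist1h1c from 5.25 ± 6.53 to 30.3 ± 15.5 and Hist2h3c1 from 0.264 ± 0.457 to 6.25 ± 3.49, and Hist1h4d fell from 75.03 ± 27.0 to 23.8 ± 15.4. Without null replicate 1, 0 of them rose and 1 fell set-adjusted, and 2 or 3 rose without any other library. The histone list had camera adjusted p = 0.927 and 0.564, and its median (-0.21) and mean (0.31) log2 ratios differed in sign with group alone.

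**Figure D3:**
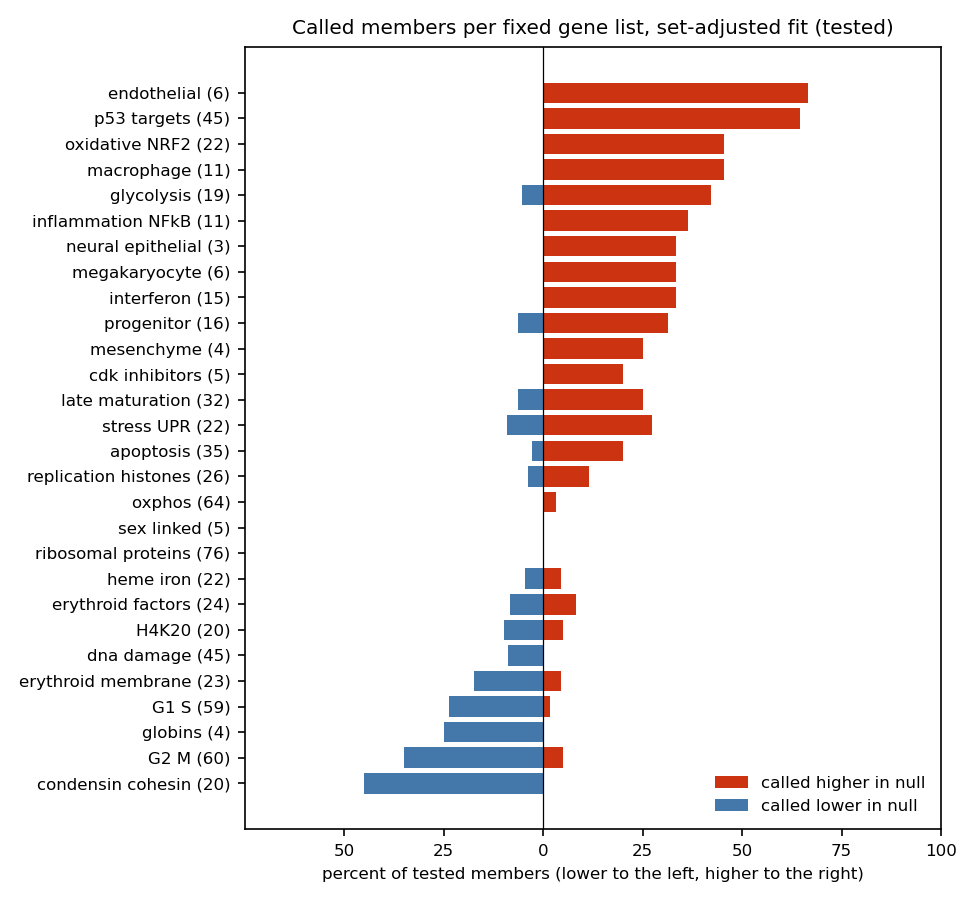
Share of tested members called higher (red, to the right) or lower (blue, to the left) in Setd8 null cells in the set-adjusted fit, in percent of tested members, for each fixed list with at least 3 tested members, whose number is in brackets. The 6 tested of 17 listed endothelial markers reached 66.7% higher, the 45 tested of 51 p53 targets 64.4% higher, and the 20 condensin and cohesin genes 45.0% lower. Endothelial markers near 0 in controls were tested only where null libraries had reads, which favours their share called higher.

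Some markers of macrophages and endothelium rose in null cells, most of them to low levels, and by camera no other marker list was called in both fits. By fry the neural and epithelial list was called higher in both (adjusted p = 0.038 with group alone and 0.0077 set-adjusted). Fry called the megakaryocyte list higher set-adjusted (adjusted p = 0.0077) and not with group alone (adjusted p = 0.078). Of 11 tested macrophage markers, 1 rose with group alone (4 adjusted over the list alone) and 5 set-adjusted (9 adjusted over the list alone). Cd68 rose in both fits, and Csf1r (0.527 ± 0.913 to 11.2 ± 6.00 CPM) and Fcgr3 (0.124 ± 0.215 to 6.91 ± 7.04 CPM) set-adjusted. The list had camera adjusted p = 1.17e-06 and 8.93e-05, and 0.147 and 0.242 with an estimated correlation. Of 6 endothelial markers, 0 passed with group alone (4 rose adjusted over the list alone) and 4 rose set-adjusted (5 adjusted over the list alone), among them Pecam1 (0.104 ± 0.142 to 2.94 ± 0.994 CPM) and Eng, which had 3 control reads and a ratio of 51.0 with a 95% counting interval of 17.2 to 249.6. This list had camera adjusted p = 0.000415 and 0.00864, and 0.0607 and 0.242 with an estimated correlation. Of 6 tested of 15 listed megakaryocyte markers, 0 passed with group alone (2 rose adjusted over the list alone) and 2 rose set-adjusted (2 adjusted over the list alone), Itga2b (12.3 ± 7.52 to 51.3 ± 15.3 CPM) and Itgb3 (16.5 ± 7.01 to 48.2 ± 6.69 CPM), with camera adjusted p = 0.104 and 0.125. Of 4 tested of 14 listed mesenchymal markers 1 rose in both fits and adjusted over the list alone, Sparc, with 3 control reads and a ratio of 109.9 (95% counting interval 37.3 to 535), and the list had camera adjusted p = 0.0489 (0.205 with an estimated correlation) and 0.132. Of 3 tested of 12 listed neural or epithelial markers, 0 passed with group alone (1 rose adjusted over the list alone) and 1 rose set-adjusted, also adjusted over the list alone, Krt18 (0.372 ± 0.644 to 11.7 ± 6.90 CPM), with camera adjusted p = 0.104 and 0.0794. Of 2 tested of 15 listed granulocyte and mast cell markers, 0 passed with group alone (2 rose adjusted over the list alone) and 1 rose set-adjusted (1 adjusted over the list alone), Ltf, from 0.918 ± 0.891 to 69.6 ± 16.7 CPM. Of 2 tested of 6 listed genes of definitive red cells, 0 passed with group alone (2 rose adjusted over the list alone) and 1 rose set-adjusted (2 adjusted over the list alone), Cd24a, from 105 ± 30.2 to 207 ± 21.6 CPM, and the 1 tested of 20 listed hepatic or endodermal markers did not pass in either fit. Of 5 sex-linked genes, 0 passed in either fit, also adjusted over the list alone (camera adjusted p = 0.239 and 0.144), with Xist at 104 ± 104 CPM in controls and 3.83 ± 5.14 in null cells and Eif2s3y at 18.4 ± 31.8 and 79.9 ± 10.4. Without null replicate 1, 0 macrophage, megakaryocyte, mesenchymal, endothelial or neural and epithelial markers passed set-adjusted, and without control replicate 1 or null replicate 2, 0 of the last 2 groups. Macrophage markers that passed numbered 2 without control replicate 1 or null replicate 3, and without control replicate 1, 4 sex-linked genes rose. Without null replicate 1 or control replicate 3, 0 granulocyte and mast cell markers and 0 genes of definitive red cells passed, nor did any of the former without null replicate 3 or of the latter without null replicate 2.

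The control genotypes were compared as values only, since 1 library carried floxed alleles without Cre. Cdkn1a stood at 5.33 CPM in the floxed control and at 11.7 and 12.05 in Cre control replicates 1 and 3. Mdm2 stood at 14.3 against 22.7 and 39.5 CPM, and Ccng1 at 28.3 against 43.6 and 68.4. Dcxr went the other way, at 7.30 against 2.52 and 5.40 CPM. In the unlettered set, Setd8 stood at 73.9 CPM in the Cre control and 74.8 in the floxed control, and the Spearman correlation across genes of log CPM between these libraries was 0.957. The other correlations between control libraries were 0.870 and 0.876, and those between null libraries 0.838, 0.835 and 0.950, with the highest in each group inside a title set.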

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

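Sex as a term and the alternatives of the set-adjusted fit, other than its list tests, were chosen after the data were examined; the cause of a shift was not tested unless it is stated. With group alone, RLE, upper-quartile, unscaled totals, globin removal and the non-robust fit gave 101 to 132 genes higher and 1 lower, not all of them the genes called before (Nqo1 did not pass with RLE, globin removal or unscaled totals, nor Ccnd2 with the last). Higher and lower genes numbered 697 and 197 with DESeq2 (684 and 164 past 2-fold), 602 and 55 with edgeR's exact test (602 and 55), 1469 and 776 with limma-voom (1386 and 529), 264 and 16 without a filter (264 and 16), 43 and 1 with 10 counts in every library (43 and 1; fewer genes tested), 909 and 437 with the title set (775 and 172), 0 and 0 with sex (0 and 0 by edgeR quasi-likelihood, 915 genes at unadjusted p under 0.05, with 9 lists higher and 7 lower) and 161 and 62 with both (161 and 62). Leaving out 1 library gave 3 to 109 higher and 0 to 2 lower, the same past 2-fold, and 10 to 13 lists higher and 5 to 7 lower. Set-adjusted, leaving out 1 library gave 162 to 869 higher and 40 to 734 lower (160 to 734 and 26 to 399 past 2-fold), and library totals gave 898 higher and 255 lower, a lower share of 22.1% against 32.5%. In that fit DESeq2 gave 1262 and 882 (1034 and 293 past 2-fold), no filter 1139 and 723 (948 and 270), and 10 counts in every library 539 higher past 2-fold. With library totals the median log2 ratio of all genes was 0.32, against 0.13. Camera with an estimated correlation called 0 lists higher and 0 lower in both fits. Setd8 passed with the title set (-0.83), did not with title set and sex (-0.72, adjusted p = 0.2345), turned to 0.16 with limma-voom and 0.15 with sex, and ranged from -0.78 to 0.066 over the leave-one-out fits, turning without control replicate 3. Other log2 ratios that turned: Car2 -0.021 with RLE and DESeq2, -0.012 without globins, -0.66 with limma-voom and -0.46 with sex; Alas2 0.058 with 10 counts in every library, 0.17 with library totals, 0.090 with the title set and 0.10 with title set and sex; with library totals also Pcna 0.011 and Rpl4 0.00033; with limma-voom also Rplp0 -0.71, Blvrb -0.065, Tcf3 0.98 and H2afx 2.26; with sex also Rplp0 -0.30, Xist 2.36, Tcf3 1.51 and H2afx 2.54; with the title set also Klf1 -0.18, Rpl4 0.16 and Atp5b -0.17; with title set and sex also Gata1 0.058, Klf1 -0.36, Ncoa4 -0.070, Rpl4 0.22 and Xist 2.23. Over the leave-one-out fits, ranges that crossed 0 were -0.20 to 0.039 (Alas2), -0.60 to 0.017 (Rpl4), -0.53 to 0.33 (Car2), -0.64 to 0.31 (Rplp0), -1.03 to 1.04 (Tcf3), -1.39 to 2.62 (H2afx), -0.062 to 0.59 (Blvrb), -0.0088 to 0.45 (Ncoa4), -0.040 to 0.20 (Atp5a1), -0.025 to 2.32 (Klf1) and -0.067 to 0.96 (Atp5b). Set tests of lists turned direction, with these median log2 ratios: oxidative phosphorylation 0.26 (10 counts in every library), 0.13 (DESeq2), 0.18 (exact test and fry), 0.31 (totals), 0.23 (title set), 0.40 (title set and sex) and -0.20 to 0.26 (leave-one-out); replication histones -0.26 (RLE and no globins), -0.23 (upper quartile), -0.21 (fry), 1.42 (limma-voom), 1.48 (sex) and -0.39 to 1.65 (leave-one-out); sex-linked genes 1.39 (DESeq2) and 1.48 (exact test); ribosomal proteins 0.18 (title set) and 0.36 (title set and sex); erythroid factors -0.088 (title set), -0.051 (title set and sex) and -0.0075 to 0.78 (leave-one-out); lysine 20 methylation genes 0.20 (limma-voom); and mesenchymal markers -0.99 (no filter). Of 89 named genes called set-adjusted, all 89 had the same direction in every leave-one-out fit and 31 kept the call in every one, with 55 calls lost without null replicate 1. No paired analysis was possible because the labels give the groups no shared replicate numbers. The exact test and the sex term were not run set-adjusted, except for the fit with both terms, and leaving out the floxed control is the fit without control replicate 2. With sex beside group, the contrast rested on control replicate 1 as its only control.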

Other observations

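The gene groups and genes of the first paragraph, the tests of cell types and the test of spread from the title sets were chosen after the results were seen. Genes of the lysosome and of ribosome assembly were listed because some members had been seen among the calls, so that the counts over them describe these libraries and test nothing, and a shift of either group is a hypothesis. Of 51 tested lysosomal genes, 3 were higher with group alone and 22 set-adjusted, and 0 were lower in either fit. The protease Ctsd stood at 364 CPM in controls and 1027 in null cells (set-adjusted log2 ratio 1.63, SE 0.14), the sterol carrier Npc2 at 30.6 and 119 (2.15, SE 0.22) and Cd63 at 4.64 and 51.7 (3.52, SE 0.42), while Ctsb did not pass at 762 and 685. Macrophages also express lysosomal genes, and some macrophage markers rose beside them. Of the lysosomal genes 1 was on the macrophage list, and 36 stood at 5 CPM or more in controls. Ctsd rose by 664 CPM and the 6 abundant macrophage transcripts named below together from 2.04 to 26.1 CPM (0.144, 0 and 5.99 in control replicates 1, 2 and 3 and 11.4, 15.9 and 50.97 in null replicates 1, 2 and 3, so that control replicate 3 and null replicate 3 carry most of these means), and a part of macrophages in the lysosomal increase stays open. Of 51 tested ribosome assembly genes, 0 passed with group alone (edgeR quasi-likelihood; 20 at unadjusted p under 0.05) and 22 were lower set-adjusted, among them Nop58 (330 to 130 CPM, log2 ratio -1.19, SE 0.15), nucleolin, Ncl (1170 to 711 CPM, -0.71, SE 0.14) and Ddx10 (44.2 to 13.2 CPM, -1.62, SE 0.28). Outside any list, the steroid dehydrogenase Hsd3b6, whose reads may be shared with close relatives, stood at 474 CPM in controls and 7785 in null cells (log2 ratio 4.04), and the secreted glutathione peroxidase Gpx3 at 0.275 and 430.9 CPM (log2 ratio 10.33), both called with group alone.

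The title sets differed in 3001 genes. Transcript length had a Spearman rho of -0.058 across genes with the difference between sets, inside the bound set beforehand for no relation. Genes lower in the unlettered set overlapped a gene on the opposite strand 0.783 times as often as genes with no call (14.0% against 17.9%). These values argue against a trend with length and against strand-blind counting of a whole set as the whole cause. The overlap test cannot address a strand setting that differed between libraries of the same set. Control replicate 1 had 42.9% of reads in no feature and 0.657% ambiguous. Control replicate 2 had 7.72% and 2.17%, and null replicate 1 had 6.07% and 2.35%. The median length was 2340 bases for genes higher in the unlettered set, 2973 for genes lower in it and 3148 for genes with no call, so that both called groups were shorter, which a correlation across all genes does not show, and a part of length in this stays open. GC content had a rho of -0.195, between the bounds set for a relation and for none, so that a GC-dependent difference in library preparation may account for a part. The median log2 difference, unlettered minus lettered, was 0.16, 0.083, 0.043 and -0.47 over GC quartiles 1 to 4. The log2 ratio of null to control had a rho of 0.189 with GC with group alone and 0.112 set-adjusted. With length it was -0.132 and -0.16, so such trends were not confined to the title sets, and their cause was not tested. A different annotation, sequencing run or stage of the embryos was not tested, and no biological explanation was tested because the labels name no difference between the sets.

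Some macrophage and endothelial markers were higher in null cells (5 of 11 and 4 of 6 set-adjusted, with neither list called at an estimated correlation), which may come from a few cells of other types inside the sort. For the abundant macrophage transcripts Lyz2, C1qa, C1qb, C1qc, Ctss and Tyrobp, 16 of 18 values in null libraries lay above every control, with Lyz2 in null replicate 2 at 0.0515 CPM and C1qc in null replicate 1 at 1.80 CPM as the exceptions, so macrophages attached to erythroblasts and transcription in the erythroblasts themselves cannot be told apart. A sort for Ter119 and CD71 should remove free macrophages, and 11 of the 22 listed macrophage markers had enough reads to be tested. Among hepatic, mesenchymal and neural or epithelial markers, 37.5% of 8 tested genes had all null libraries above all controls, against 70.6% of 17 tested macrophage and endothelial markers, too few to decide on a general loss of purity. Only 1 of 20 hepatic, 4 of 14 mesenchymal and 3 of 12 neural or epithelial markers were tested, and 6 of 17 endothelial ones. Markers near 0 in controls were tested only where null libraries had reads, which favours both shares.

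More genes were higher than lower in null cells, 120 against 1 with group alone. With the title set in the model 32.5% of calls were lower, which is consistent with the spread between sets having hidden the smaller decreases in the fit with group alone. The balance depends on the test as well, since with group alone 22.0% of calls were lower by DESeq2, 8.37% by edgeR's exact test and 34.6% by limma-voom, none of which had the title set as a term. Higher genes outnumbered lower ones under every scaling tried. The share of lower calls in the set-adjusted fit ran from 22.1% (library totals) to 38.8% (globin genes removed), so the size of the excess moved with the scaling. All of these scalings give relative abundance only, so trying them cannot exclude scaling as a part of the cause. An effect of the loss of Setd8, the difference the design names, on this balance stays open, untested and confounded in part with sex.

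The 6 libraries make 10 splits of 3 against 3, so no share under 0.1 can be had. With group alone the real split called 121 genes and the highest other 2024, from the split that follows the title sets, which points to a structure of the samples; 2 of 10 splits reached the real count, also past 2-fold (121 against 1804). For lists the real split called 19 and the highest other 11, with 1 of 10 reaching the real count. Set-adjusted, 9 splits could be fitted, and the real split gave 1346 genes, 947 past 2-fold and 18 lists, against at most 0, 0 and 16 in the others, with 1 of 9 as large in each case.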
